A study of Escherichia coli str. K-12 substr. MG1655 with 16 samples.

How the data were processed

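RNA of 16 Escherichia coli K-12 MG1655 cultures was sequenced, 2 biological replicates of each of 8 genotypes per the labels. Per the labels' protocols, cells were grown in 100 mL LB at 37 °C to mid-exponential phase (an OD600 of 0.5 for the hns stpA double mutant and 0.9 for the others), RNA was extracted with TRIzol and treated with DNase, mRNA was enriched with MICROBExpress, and libraries were made with TruSeq and sequenced on a HiSeq instrument. The authors deposited 1 file of read counts per library, whole numbers per gene with no header. Per the submitters' processing notes, BWA and edgeR were used, without versions or roles. The genome build, annotation, counting tool, handling of strand and filters are not given in the sources used here. Without a statement on strand, reads of overlapping and antisense genes cannot be told apart, so values of such genes are uncertain, as are those of near-identical genes such as gadA and gadB.

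The files list 4245 genes by locus tag, and 4188 of them matched a symbol in the RefSeq table of assembly ASM584v2, which was used only for names and the order of neighbouring genes. The other 57 kept their locus tag. The files hold 0 rRNA and 0 tRNA genes, so the planned removal of rRNA genes removed nothing. Total counts per library ran from 419223 to 1173501, with a median of 810777.5, and 3 counts were taken as the limit that a count of 0 allows, per library. Poisson and counting intervals are exact 95% intervals.

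Counts were fitted with edgeR 4.0.16 (R 4.3.3) in 1 model of all 16 libraries with a term per group, after filterByExpr and with TMM scaling. All groups shared 1 estimate of the spread because 2 libraries per group leave too few residual degrees of freedom alone. The filter left 3812 genes and removed 433, and the common biological coefficient of variation was 14.8%. Each contrast was tested 2-sided with edgeR's quasi-likelihood F test and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. The contrasts were each mutant against wildtype, each double mutant against the hns mutant, and 3 interactions, such as the change from hns to hns stpA minus the change from wildtype to stpA. Standard errors were derived from the log2 fold change and its F value. Levels are CPM scaled by TMM, except in the plot of the deleted genes, which uses totals.

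Gene lists were fixed before the data were examined, 28 lists with 556 names, of which 541 were in the files: nucleoid proteins and co-regulators, glutamate-dependent acid resistance, flagella and chemotaxis, type 1 fimbriae, cryptic chaperone-usher fimbriae, curli, cryptic beta-glucoside operons, CRISPR-Cas, type II secretion, the remnant type III secretion cluster, activators silenced by H-NS, O-antigen and lipopolysaccharide core, 6 prophages (Rac, e14, Qin, DLP12, CP4-6, CP4-57), proU, carnitine metabolism, lysine and arginine acid resistance, the maltose regulon, colanic acid, RpoS markers, heat shock, ribosomal proteins, ATP synthase with NADH dehydrogenase I, and the genes beside the deleted genes. Each list was tested with limma's (3.58.1) camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over all 364 tests of lists and contrasts. Camera called 157, of which 11 were also called with an estimated correlation and 127 by fry, which does not compare a list with other genes. The 11 are CRISPR-Cas in the hns, hns hha and hns ydgT mutants against wildtype, colanic acid in the hns stpA mutant against wildtype and against the hns mutant and in the stpA interaction, acid resistance in the stpA mutant, type 1 fimbriae in the hha mutant and the hha interaction, curli in the hns hha mutant against the hns mutant, and the genes beside the deleted genes in the hha interaction.

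The text names the 4 deleted genes, members of the lists (preferring the up to 4 with the smallest adjusted p), and the 10 highest and 10 lowest log2 fold changes of the hns and hns stpA mutants against wildtype and of hns stpA against hns, or the 5 highest and 5 lowest of other contrasts, among called genes with a mean of at least 10 CPM in 1 group and both libraries of one group beyond both of the other. Genes of and beside the run without counts in the stpA mutant were named after their values were seen. Overlaps of calls were set beside the product of the list sizes over the genes tested and beside 20 simulations of unchanged groups. In these all counts were redrawn and both groups shared 1 simulated control. Unchanged groups have few calls by construction, so these simulations cannot show how far shared controls raise the overlap of changed groups.

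The test was checked on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For the ydgT mutant against wildtype edgeR recovered 48% and 84%, with 11 false among 143 calls over 3780 genes, and for the ydgT interaction 15% and 69%, with 8 false among 92 calls. Alternatives were DESeq2 1.42.0, median-ratio size factors, no low-count filter, a log2 fold change of at least 1, the replicate number as a block, only the compared groups, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables, and matplotlib 3.10.9 for figures.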

Results

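The series measured messenger RNA in Escherichia coli K-12 MG1655, a laboratory strain, and in 7 mutants derived from it. H-NS is a DNA-binding protein of the bacterial nucleoid that silences many genes, StpA is its paralogue, and Hha and YdgT (cnu in the RefSeq annotation) are small proteins that bind H-NS and StpA. The strains were wildtype, single deletions of hns, stpA, hha and ydgT, and double deletions of hns with stpA, hns with hha and hns with ydgT. Each of the 8 groups had 2 libraries, which the labels call biological replicates, so 16 libraries were compared. All strains grew in 100 mL LB at 37 °C and were taken in mid-exponential phase, the hns stpA double mutant at an OD600 of 0.5 and the others at 0.9. Total counts ran from 419223 to 1173501 per library over 4245 genes, and 3812 genes passed the low-count filter and were tested. The first principal component of log2 CPM, which separated the strains with hns from those without, held 72.5% of the variance. The second, on which the hns stpA double mutant stood apart, held 10.8%. Below, log2 fold changes are given ± their standard error, from 2 libraries against 2, or from 2 libraries of each group for interactions. This error uses a spread estimated over all 16 libraries, so it is not the spread of the compared libraries alone. Expression levels are given as TMM-scaled CPM, which put the library totals on a common scale, ± SD with n = 2.

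The deleted genes were read first, as a check of the labels. In the 8 libraries labelled with an hns deletion, hns (locus b1237) had 0 counts, apart from 1 count in replicate 1 of the hns hha double mutant, and it had 259 to 875 counts in the other 8 libraries. The stpA gene (b2669) had 2 and 3 counts in the wildtype libraries and 0 in both stpA mutant libraries, so the deletion cannot be read from these counts alone. It had 272 and 310 counts in the hns mutant against 2 in each hns stpA library, which the label of the double mutant requires. Residual hha (b0460) counts were present in the hha mutant (37 and 19, against 60 and 95 in wildtype) and in the hns hha double mutant (20 and 8, against 570 and 725 in the hns mutant). The stpA mutant, which keeps the gene, held 21 and 33, so these counts check the hha deletion in the double mutant and not in the single one. The cnu gene (b1625) had 0 and 1 counts in the ydgT mutant against 3 and 5 in wildtype, too few to check, and 0 in both hns ydgT libraries against 21 and 39 in the hns mutant. The limit that a count of 0 allows is 3 counts, worth 2.56 to 7.16 CPM over these libraries, and intervals and floors cover counting error only.

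**Figure D1:**
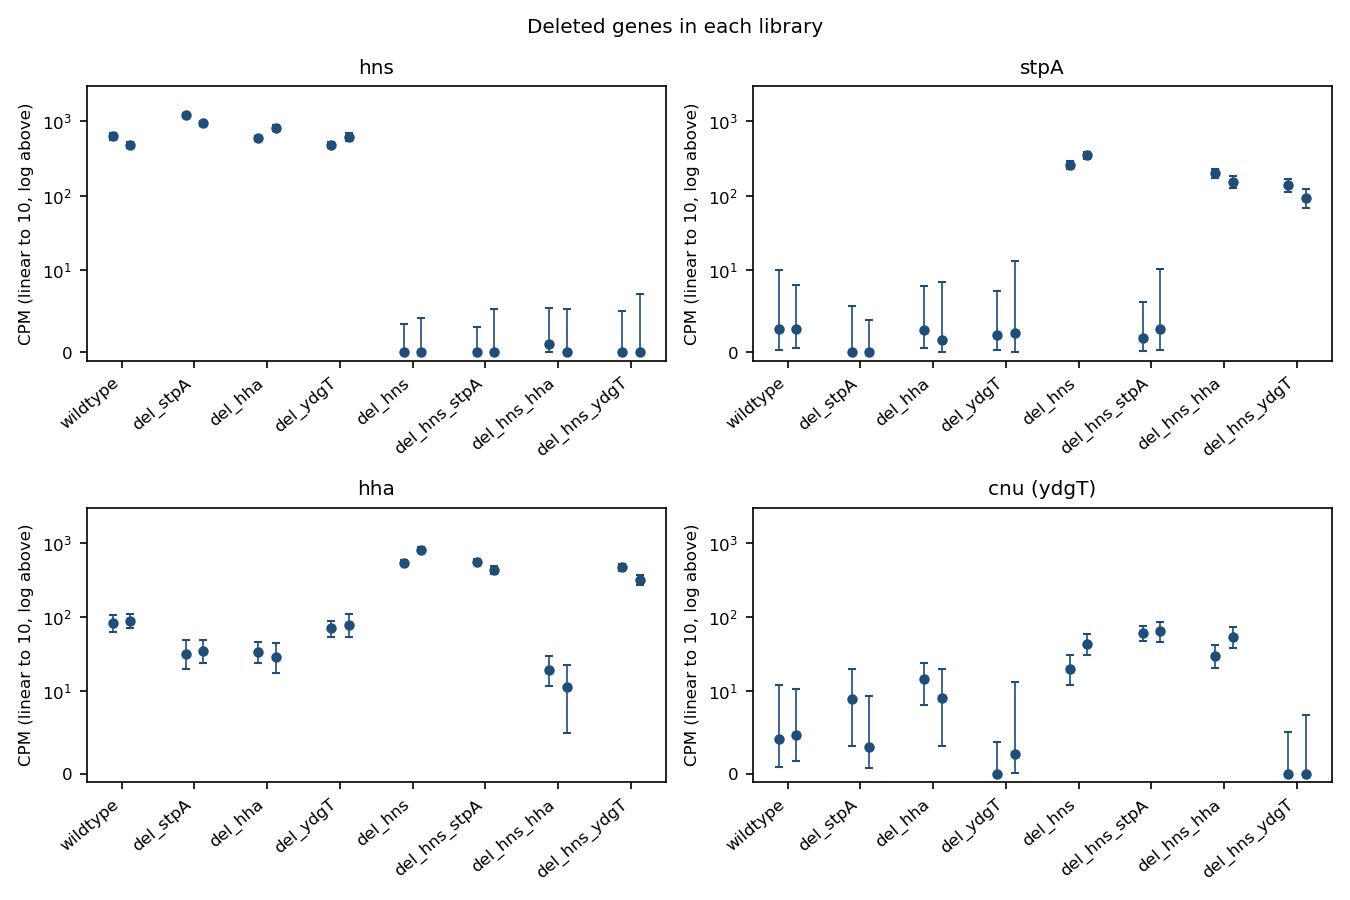
CPM of hns, stpA, hha and cnu (ydgT) in each library (points, 2 per group) with exact 95% Poisson intervals, on an axis that is linear to 10 CPM and logarithmic above. The hns counts are 0 or 1 in the 8 libraries labelled with an hns deletion, and stpA, hha and cnu are higher in hns mutants that keep them than in wildtype.

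The first comparison asked what the loss of H-NS alone does to the transcriptome. In the hns mutant 1160 genes were higher and 771 lower than in wildtype (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 3812 genes tested). Among the highest was hlyE, which encodes a pore-forming haemolysin, at 6794 ± 511 CPM against 9.98 ± 7.38 CPM. The Cascade genes casA (2188 ± 11.2 CPM against 7.56 ± 2.77 CPM) and casB (1236 ± 35.0 CPM against 0 counts in wildtype, at least 414-fold higher against a floor of 3 counts per library) rose with it. The regulator gene ydeO had 307 ± 158 CPM and 1 count in wildtype, a ratio of 618 (95% counting interval 110.3 to 24454). The genes ynbB, fepE, ydeQ, ybeR, yibG and b1935 had 0 counts in wildtype and were at least 14.5 to 15.9-fold higher. Among the lowest, apart from hns itself, were mtr, a tryptophan permease (19.0 ± 7.29 CPM against 1224 ± 30.7 CPM), and the succinate dehydrogenase genes sdhC (-5.51 ± 0.33), sdhA (-4.73 ± 0.29) and sdhD (-4.68 ± 0.32). Also among them were the neighbouring yjiH (-5.40 ± 0.39) and yjiG (-5.24 ± 0.31), the glutamine transporter gene glnP (-4.75 ± 0.40), yeaC (-4.50 ± 0.33) and the proline dehydrogenase gene putA (-4.35 ± 0.40). The co-regulator genes rose as well, stpA by 7.21 ± 0.35, hha by 3.51 ± 0.25 and cnu by 3.30 ± 0.59.

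Many of the gene lists fixed before the data were examined had most of their members changed in 1 direction in the hns mutant. All 15 glutamate-dependent acid resistance genes rose, with a median log2 fold change of 2.96 (camera adjusted p = 1.17e-12, adjusted p = 0.0893 with an estimated correlation). They include yhiM (4.75 ± 0.25), gadW (4.02 ± 0.28) and gadA (5.89 ± 0.24). The gadA and gadB genes are near-identical and reads may have been split between them, so their separate values are uncertain. All 9 type 1 fimbriae genes rose (camera adjusted p = 2.96e-09, adjusted p = 0.0525 with an estimated correlation), including the recombinase genes fimB (4.53 ± 0.28) and fimE (6.12 ± 0.40) and the usher gene fimD (3.80 ± 0.22). Of 42 tested genes of cryptic chaperone-usher fimbriae 33 rose and none fell (camera adjusted p = 3.08e-09, adjusted p = 0.0989 with an estimated correlation), with elfC at 4.47 ± 0.29 and yadC at 4.98 ± 0.36. All 6 tested curli genes rose (camera adjusted p = 5.11e-04, adjusted p = 0.115 with an estimated correlation), with csgD, their activator, at 3.87 ± 0.30. All 8 CRISPR-Cas genes rose, the list with the highest median, 6.89 (camera adjusted p = 1.66e-21, adjusted p = 0.0444 with an estimated correlation). All 9 activators on the list of H-NS-silenced regulators rose (camera adjusted p = 1.48e-06, adjusted p = 0.146 with an estimated correlation), with leuO at 4.07 ± 0.28 and adiY at 5.14 ± 0.26. All 3 proU genes rose (camera adjusted p = 1.07e-06, adjusted p = 0.0893 with an estimated correlation), with proV at 5.98 ± 0.24. All 10 carnitine metabolism genes rose (camera adjusted p = 4.84e-04, adjusted p = 0.138 with an estimated correlation), with fixB, with few wildtype counts, at a ratio of 117 (95% counting interval 32.0 to 977). All 4 genes of lysine and arginine acid resistance rose (camera adjusted p = 1.24e-04, adjusted p = 0.0525 with an estimated correlation), with cadA at 5.41 ± 0.43. Of 14 type II secretion genes 11 rose (camera adjusted p = 0.00121, adjusted p = 0.144 with an estimated correlation), with gspD at 4.58 ± 0.30. Of 10 genes of the remnant type III secretion cluster 9 rose (camera adjusted p = 0.00487, adjusted p = 0.538 with an estimated correlation), with yqeI at 4.67 ± 0.40. Of 14 genes of cryptic beta-glucoside operons 10 rose and 1 fell (camera adjusted p = 0.00287, adjusted p = 0.171 with an estimated correlation), with bglB at 7.02 ± 0.37. Of 20 RpoS stationary-phase markers 16 rose (camera adjusted p = 4.86e-05, adjusted p = 0.396 with an estimated correlation), with osmB at 4.37 ± 0.26. In the other direction, all 22 genes of ATP synthase and NADH dehydrogenase I fell, with a median of -1.63 (camera adjusted p = 1.32e-10, adjusted p = 0.174 with an estimated correlation). The atpD gene changed by -1.78 ± 0.19 and nuoM by -1.89 ± 0.22. Of 54 ribosomal protein genes 40 fell and none rose, with a median of -0.71 (camera adjusted p = 3.07e-05, adjusted p = 0.613 with an estimated correlation), rplM at -1.13 ± 0.19. The ribosomal count was 22 without hns mutant replicate 2 and 24 without wildtype replicate 2, and 2 of these genes were higher without hns mutant replicate 1. The beta-glucoside gene that fell was not called without hns mutant replicate 1 or either wildtype library, nor by DESeq2.

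Some prophage genes were also higher in the hns mutant. In the Rac prophage 16 of 22 tested genes rose (camera adjusted p = 0.00398, adjusted p = 0.398 with an estimated correlation), with recE at 3.11 ± 0.28. In DLP12 9 of 13 rose (camera adjusted p = 0.0112, adjusted p = 0.524 with an estimated correlation), with ompT at 3.45 ± 0.26. The Qin (10 of 18 higher, 1 lower), e14 (5 of 10 higher, 1 lower), CP4-57 (5 of 13 higher) and CP4-6 (5 of 17 higher, 3 lower) prophages had no camera call. The same holds for flagella and chemotaxis, of which 21 of 54 genes had enough counts (1 higher, 4 lower, with flhC at -1.60 ± 0.36). It also holds for heat shock (4 of 15 higher), the maltose regulon (7 of 10 higher, malT at -1.27 ± 0.19) and colanic acid (11 of 20 higher). It further holds for O-antigen and lipopolysaccharide core (13 of 20 higher), nucleoid proteins and co-regulators (7 of 12 higher, 2 lower) and the genes beside the deleted genes (6 of 9 higher, 1 lower). Adjusted over the list alone, the counts were the same except for cryptic fimbriae (35 higher), e14 (6 higher), colanic acid (12 higher), RpoS markers (17 higher and 1 lower), ribosomal proteins (1 higher) and nucleoid proteins (3 lower). Without hns mutant replicate 1, flagella had 2 lower, no e14, Qin or CP4-6 gene was lower, and no heat shock gene was called. O-antigen and core had 6 higher without hns mutant replicate 2 and 7 without wildtype replicate 1. Without wildtype replicate 1, CP4-6 had 1 lower and no heat shock gene was called. Without wildtype replicate 2, no e14 gene was lower, CP4-6 had 3 higher and 5 lower, and heat shock had 1 higher and 1 lower. DESeq2 called 1 flagellar gene and no e14, Qin or CP4-6 gene lower.

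The next comparison asked what StpA does while H-NS is present. In the stpA mutant 258 genes were higher and 242 lower than in wildtype (edgeR, adjusted p under 0.05), although wildtype held only 2 and 3 stpA counts. The highest were genes of anaerobic threonine degradation, tdcE (6959.7 ± 1624 CPM against 151 ± 74.3 CPM), tdcD (5.26 ± 0.30) and tdcG (4.86 ± 0.30), and of galactarate use, garL (4.96 ± 0.62) and garP (4.83 ± 0.74). The SDs of garL (282 ± 267 CPM) and garP (136 ± 141 CPM) were near their means. The lowest were genes of the glutamate and aspartate transporter, gltI, gltJ, gltK and gltL, and the neighbouring ribonucleoside hydrolase gene rihA. They had 0 counts in both stpA mutant libraries and were at least 68.9, 17.4, 11.3, 17.7 and 56.3-fold lower in that order. They belong to a run of 9 neighbouring genes (ybeT to gltI) with 0 counts in both libraries of this strain, against 1384 counts in the 2 wildtype libraries. Its first gene, ybeT, also had 0 counts in wildtype and tells nothing, so the loss is read from the 8 genes from ybeU to gltI. No other mutant group had a run of 3 or more genes at 0 with at least 30 wildtype counts in total. The run holds 8 of the 242 lower genes. Acid resistance rose in 12 of 15 genes (camera adjusted p = 8.92e-29, adjusted p = 0.0404 with an estimated correlation), with gadA at 4.08 ± 0.22 and yhiM at 3.63 ± 0.25. Lysine and arginine acid resistance rose in 3 of 4 (camera adjusted p = 1.30e-04, adjusted p = 0.0525 with an estimated correlation), with cadB at 3.37 ± 0.44. Of 15 heat shock genes 10 rose (camera adjusted p = 5.07e-11, adjusted p = 0.125 with an estimated correlation), with the chaperone gene dnaK at 2.16 ± 0.24 and groS at 1.64 ± 0.21. Of 20 RpoS markers 10 rose while 1 fell (camera adjusted p = 6.82e-04, adjusted p = 0.477 with an estimated correlation), with elaB at 1.83 ± 0.20. Adjusted over the list alone these 4 lists had 13 higher and 0 lower, 3 higher and 0 lower, 12 higher and 0 lower and 11 higher and 2 lower. The hns gene itself was higher (1.08 ± 0.22, 1001 ± 130.3 CPM against 473 ± 85.2 CPM) and hha lower (-1.22 ± 0.30). The call for hha was lost without stpA mutant replicate 1, those for hha and hns without wildtype replicate 2, and 5 RpoS markers rose without stpA mutant replicate 2 or wildtype replicate 1. The lower RpoS call was lost without stpA mutant replicate 1 or wildtype replicate 1, and 2 were lower without stpA mutant replicate 2. The count of calls fell to 291 without wildtype replicate 1 and to 323 without wildtype replicate 2.

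**Figure D2:**
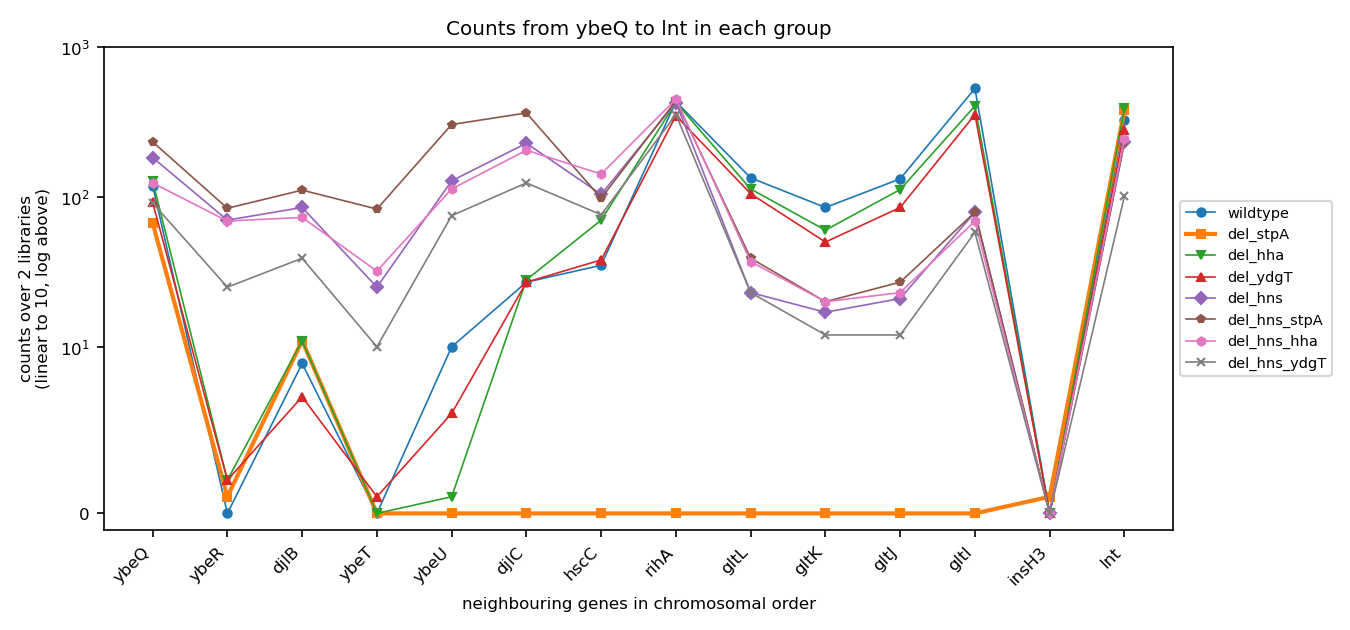
Counts summed over the 2 libraries of each group for 14 neighbouring genes from ybeQ to lnt, in chromosomal order, on an axis that is linear to 10 counts and logarithmic above. In the stpA mutant the 9 genes from ybeT to gltI have 0 counts, as ybeT does in wildtype, and ybeQ (67 counts) and lnt (381 counts), the nearest genes of at least 10 CPM in wildtype, do not, while the hns stpA double mutant has counts in all 9.

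Few genes were called in the hha mutant against wildtype. In it 11 genes were higher and 1, hha itself, was lower (-1.47 ± 0.30, adjusted p = 0.036; edgeR). The higher genes included tomB, which lies beside hha and encodes a protein that counters it (498 ± 55.5 CPM against 127 ± 3.24 CPM), and maa on the other side (1.11 ± 0.21). Of the type 1 fimbriae genes 4 rose, fimD (1.58 ± 0.22), fimC (1.43 ± 0.23), fimI (1.23 ± 0.19) and fimA (0.90 ± 0.18), and none fell (camera adjusted p = 2.91e-15, adjusted p = 0.03 with an estimated correlation). Of the acid resistance genes 3 rose, dctR (1.55 ± 0.31), mdtE (1.38 ± 0.22) and mdtF (0.95 ± 0.20). Of the 15, 11 did so adjusted over the list alone (camera adjusted p = 3.27e-20, adjusted p = 0.0525 with an estimated correlation). The other higher genes were ylbH (2.26 ± 0.40) and psuG, which had 3 counts in wildtype (ratio 8.28 (95% counting interval 2.53 to 42.9)). At an unadjusted p under 0.05 there were 236 genes, where a share of 0.05 of the 3812 tested genes would pass with no change. The psuG gene was not called by DESeq2. Leaving out hha mutant replicate 1 left 1 call and replicate 2 left 6, and leaving out either wildtype library left 2. Of the type 1 fimbriae genes 0 rose without hha mutant replicate 1 and 1 without either wildtype library, and of the acid resistance genes 1 rose without hha mutant replicate 2 and 0 without any other of the 4. The calls for hha, maa, mdtE, mdtF, fimA and psuG were lost when any 1 of the 4 libraries was left out, and those for dctR, ylbH and fimC without hha mutant replicate 1 or either wildtype library. That for fimD was lost without hha mutant replicate 1 or wildtype replicate 1, and that for fimI without hha mutant replicate 1 or wildtype replicate 2.

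No gene passed the test in the ydgT mutant against wildtype (edgeR, 0 of 3812). At an unadjusted p under 0.05 edgeR gave 202 genes. With no change at all, a share of 0.05 of the 3812 tested genes would pass that limit, which is close to this number. DESeq2 called 3 at its adjusted p, 2 of them acid resistance genes, with gadC among them. Simulated data on the depths of this comparison held 100 genes changed 2-fold and 100 changed 4-fold at once, none at the lowest levels. Of these 48% and 84% were recovered over 3780 genes, so changes of 2-fold could often be missed at this depth. Where fewer genes change, the adjusted threshold is stricter, and the shares recovered would be lower. The acid resistance genes had a median log2 fold change of -0.93, with gadC at -1.16 ± 0.23 and gadA at -1.19 ± 0.25. Of the 15, 10 were lower adjusted over the list alone and none over all genes (camera adjusted p = 1.38e-22, adjusted p = 0.0525 with an estimated correlation). RpoS markers had a median of -0.50 with no gene called either way (camera adjusted p = 8.45e-11, adjusted p = 0.144 with an estimated correlation). ATP synthase and NADH dehydrogenase I genes had a median of 0.28 and 4 genes higher adjusted over the list alone (camera adjusted p = 3.78e-09, adjusted p = 0.22 with an estimated correlation).

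**Figure D3:**
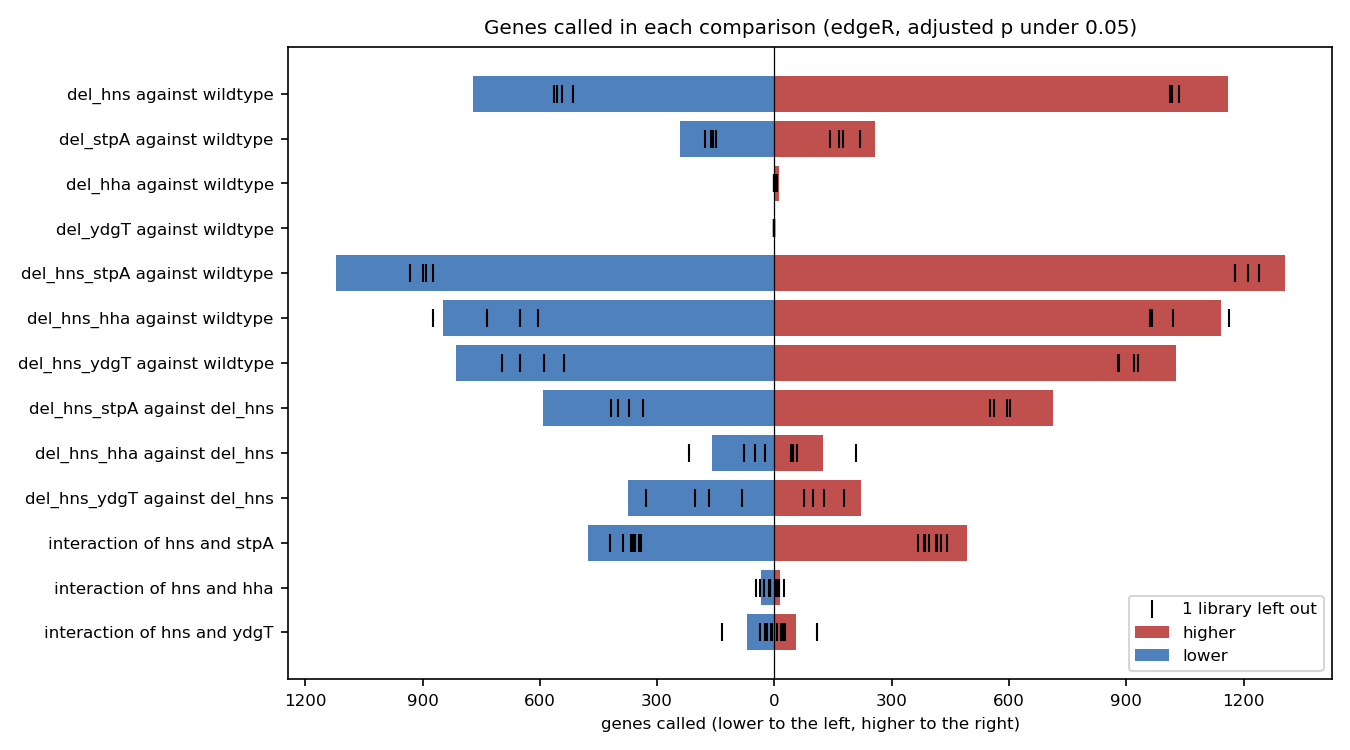
Number of genes called lower (left, blue) and higher (right, red) in each comparison, and the numbers with 1 library left out (black ticks). The del_hns_stpA comparison with wildtype has the most calls, 2427, and the del_ydgT comparison has 0.

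The double mutants were then set against wildtype. The hns stpA double mutant had the most calls, 1305 higher and 1122 lower (edgeR). Its cultures were taken at an OD600 of 0.5 and all others at 0.9, so culture density and genotype are confounded in every comparison with this strain. The fimbrial gene sfmA (1574 ± 135 CPM) and iraM, which encodes a protein that stabilises RpoS (1125 ± 104 CPM), had 0 counts in wildtype and were at least 527 and 377-fold higher. The porin gene ompN had 1605 ± 109.7 CPM, and ygeF of the remnant type III secretion cluster 659 ± 21.8 CPM against 1 count in wildtype, a ratio of 1386 (95% counting interval 248 to 54778). The glycolate oxidase genes glcD (4.25 ± 0.577 CPM against 1680.5 ± 36.9 CPM) and glcE (-6.59 ± 0.24) were lowest after hns, followed by yjiH (-6.45 ± 0.44), yjiG (-6.10 ± 0.34) and mtr (-5.44 ± 0.26). All 20 colanic acid genes rose, with a median of 6.71 (6.51 with genes at 0 counts set to their bound) (camera adjusted p = 2.33e-22, adjusted p = 0.0404 with an estimated correlation). Of 42 cryptic fimbriae genes 39 rose and 1 fell (camera adjusted p = 4.43e-19, adjusted p = 0.0788 with an estimated correlation). All 10 genes of the remnant type III secretion cluster (camera adjusted p = 1.51e-07, adjusted p = 0.197 with an estimated correlation) rose. So did 19 of 20 O-antigen and core genes (camera adjusted p = 0.00202, adjusted p = 0.609 with an estimated correlation). Examples are gmd at 8.53 ± 0.33, elfC at 7.09 ± 0.30, yqeK, with few wildtype counts, at a ratio of 452 (95% counting interval 125 to 3737) and waaY at 4.42 ± 0.31. All 15 acid resistance genes were higher here too (camera adjusted p = 4.12e-07, adjusted p = 0.192 with an estimated correlation), as were all 8 CRISPR-Cas genes (camera adjusted p = 1.65e-10, adjusted p = 0.0921 with an estimated correlation). The list of ribosomal proteins had 39 of 54 lower (camera adjusted p = 1.49e-04, adjusted p = 0.642 with an estimated correlation). Adjusted over the list alone these 7 counts were the same. Without hns stpA replicate 2 the ribosomal count was 22, and without replicate 1, or with DESeq2, no cryptic fimbriae gene fell. Of the genes higher in the hns mutant, 990 were also higher in the double mutant, where independent lists would share 397. Simulated unchanged groups against redrawn wildtype counts shared 0.05 on average. For lower genes the numbers were 610, 227 and 0, and 40 genes were called in opposite directions. Both comparisons use the same 2 wildtype libraries, too few to split, so part of the excess may come from the shared controls. The simulated groups have few calls by construction, so they do not measure that part.

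The other double mutants resembled the hns mutant more closely in their counts of calls. The hns hha double mutant had 1142 genes higher and 848 lower than wildtype, and the hns ydgT double mutant 1027 and 815 (edgeR). With DESeq2 the numbers were 1047 and 615 for hns hha, and 997 and 502 for hns ydgT. The citrate lyase gene citF reached 859.8 ± 155 CPM in the hns hha strain, against 3 counts in wildtype, with a ratio of 579.7 (95% counting interval 198 to 2815). The phospho-beta-glucosidase gene bglB reached 1243 ± 61.1 CPM in the hns ydgT strain against 2.39 ± 0.0132 CPM. The fimbrial gene elfA was at 5187 ± 3202 CPM in the hns ydgT strain, with a wide spread between its libraries. The casA gene was at 8.53 ± 0.29 and 8.57 ± 0.29, and hlyE at 8.73 ± 0.34 and 8.89 ± 0.34, in that order. Among the lowest genes were again yjiH, yjiG and mtr, with yjiG at -6.09 ± 0.34 and mtr at -5.20 ± 0.26 and -5.56 ± 0.28, and with 0 counts of yjiH in the hns ydgT strain (at least 35.8-fold lower). Ribosomal protein genes fell in 50 of 54 cases in the hns hha strain, with a median of -1.26 (camera adjusted p = 4.47e-12, adjusted p = 0.389 with an estimated correlation). They fell in 52 of 54 in the hns ydgT strain, with a median of -1.49 (camera adjusted p = 1.32e-17, adjusted p = 0.269 with an estimated correlation). The rplV gene changed by -1.86 ± 0.20 and -2.22 ± 0.21. All 15 acid resistance genes rose in the hns hha strain (camera adjusted p = 3.70e-10, adjusted p = 0.115 with an estimated correlation) and in the hns ydgT strain (camera adjusted p = 1.33e-13, adjusted p = 0.0893 with an estimated correlation). So did all 8 CRISPR-Cas genes, in hns hha (camera adjusted p = 6.88e-25, adjusted p = 0.0404 with an estimated correlation) and in hns ydgT (camera adjusted p = 7.56e-29, adjusted p = 0.0372 with an estimated correlation). The hns mutant shared 983 higher and 574 lower genes with the hns hha strain (348 and 172 for independent lists) and 925 and 476 with the hns ydgT strain (313 and 165), or 800 and 311 with it without wildtype replicate 2 (229 and 82.0). The simulated unchanged groups, with few calls by construction, shared 0 genes in these 2 cases. Part of the excess may come from the shared wildtype libraries, which these simulations cannot measure.

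**Figure D4:**
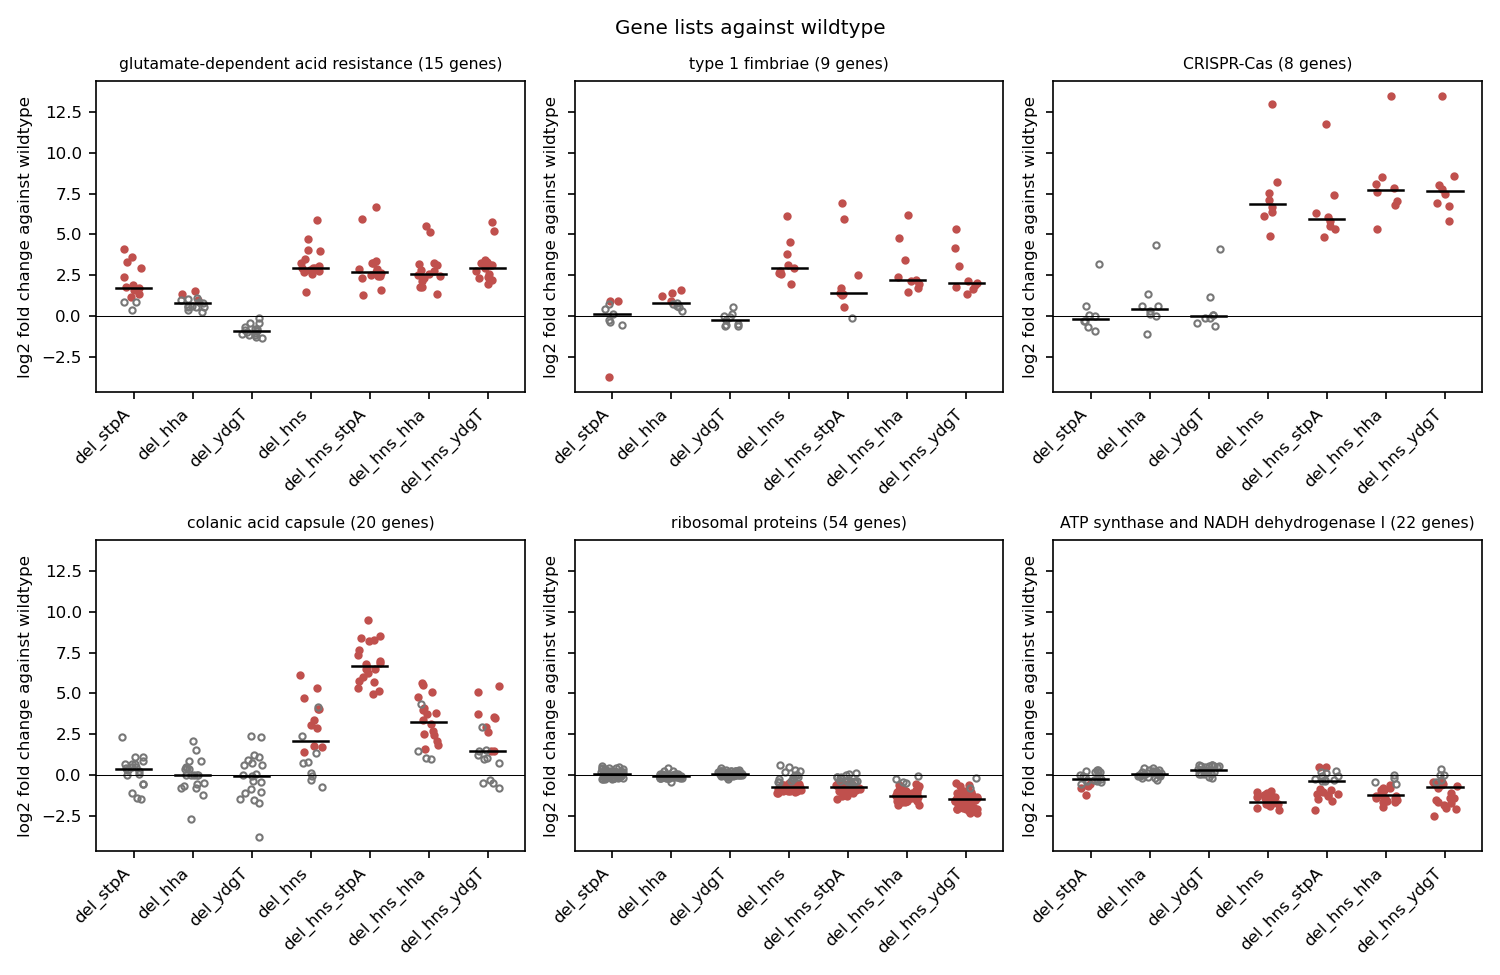
Log2 fold changes against wildtype of the tested members of 6 gene lists in the 7 mutants, filled where edgeR's adjusted p is under 0.05 and open otherwise, with the median as a bar. Colanic acid genes have a median of 6.71 (6.51 with genes at 0 counts set to their bound) in the hns stpA double mutant and 2.10 (1.73 with genes at 0 counts set to their bound) in the hns mutant. Fitted values of genes with 0 counts in wildtype, such as casB, depend on the prior count.

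Setting the hns stpA double mutant against the hns mutant asked what stpA loss does without H-NS, where stpA RNA is raised. StpA protein was not measured. In the double mutant 713 genes were higher and 592 lower (edgeR), or 649 and 327 with DESeq2. Among the highest were glpA, glpB and glpC, which encode the anaerobic glycerol-3-phosphate dehydrogenase, with glpA at 932 ± 158 CPM against 4.0 ± 2.39 CPM, glpB at 7.94 ± 0.46 and glpC at 6.64 ± 0.43. The wcaC gene of colanic acid synthesis (251 ± 4.15 CPM against 2.0 ± 1.19 CPM), sfmA (6.40 ± 0.30) and iraM (6.10 ± 0.42) were also among them. The lowest after stpA were glcD (-5.99 ± 0.29), the purine salvage genes ghxQ (-5.01 ± 0.44), guaD (-4.92 ± 0.47) and xanQ (-4.21 ± 0.38), gudP of glucarate uptake (-4.99 ± 0.91) and the anaerobic fumarase gene fumB (-4.33 ± 0.24). All 20 colanic acid genes rose, with a median of 4.50 (camera adjusted p = 1.85e-45, adjusted p = 9.43e-04 with an estimated correlation), cpsB by 4.12 ± 0.20 and wcaI by 4.27 ± 0.22. Of 42 cryptic fimbriae genes 28 rose (camera adjusted p = 6.33e-15, adjusted p = 0.0727 with an estimated correlation), as did 8 of 10 genes of the remnant type III secretion cluster (camera adjusted p = 9.71e-09, adjusted p = 0.144 with an estimated correlation). Of 10 maltose genes 8 rose (camera adjusted p = 3.80e-04, adjusted p = 0.165 with an estimated correlation), and of 15 heat shock genes 9 (camera adjusted p = 0.0399, adjusted p = 0.644 with an estimated correlation). Of 20 O-antigen and core genes 13 rose and 1 fell (camera adjusted p = 0.00106, adjusted p = 0.572 with an estimated correlation). Of 22 genes of ATP synthase and NADH dehydrogenase I 15 rose (camera adjusted p = 1.21e-04, adjusted p = 0.459 with an estimated correlation). Examples are yehB at 3.44 ± 0.23, ygeF at 5.00 ± 0.27, malK at 2.75 ± 0.23, waaY at 3.86 ± 0.31 and nuoH at 1.83 ± 0.18. Of 22 Rac prophage genes 19 fell (camera adjusted p = 4.54e-06, adjusted p = 0.115 with an estimated correlation), with sieB at -3.16 ± 0.43. Of 8 CRISPR-Cas genes 7 fell (camera adjusted p = 0.00586, adjusted p = 0.421 with an estimated correlation), with casC at -1.23 ± 0.19. Of the 9 type 1 fimbriae genes 7 fell and 2 rose (camera adjusted p = 0.00179, adjusted p = 0.115 with an estimated correlation), with fimA at -2.10 ± 0.19 and fimB at 1.44 ± 0.19. The difference in harvest density applies to all of these. The count of Rac genes was 10 without hns stpA replicate 2 and 11 with DESeq2. The rise of 1 of the 2 higher type 1 fimbriae genes was lost without that library or hns mutant replicate 2. The lower O-antigen and core call was lost without hns mutant replicate 1 or either hns stpA library and with median-ratio size factors or DESeq2, and 2 cryptic fimbriae genes fell without hns mutant replicate 1. Adjusted over the list alone the counts were the same except for cryptic fimbriae (29 higher and 1 lower) and Rac (0 higher and 20 lower). With median-ratio size factors all log2 fold changes of this comparison shifted by a median of 0.11, and by 0.12 against wildtype.

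The hns hha double mutant against the hns mutant gave 125 higher and 159 lower genes (edgeR). The balance turned with DESeq2 (79 higher and 73 lower), with only the compared groups fitted (130 and 108) and with a log2 fold change of at least 1 required (96 and 64). Among the highest was fepA, which encodes the ferric enterobactin receptor (26.7 ± 21.8 CPM against 3.42 ± 3.21 CPM). The SDs of fepA were near its means, and its mean in the hns mutant lay below the level of 3 counts in those libraries (3.47 and 4.27 CPM). After hha (-5.65 ± 0.31) the lowest was maa, which lies beside hha (9.11 ± 6.05 CPM against 176 ± 1.24 CPM), and then cadA, the lysine decarboxylase gene (-3.91 ± 0.40). The tomB gene was also lower (-1.16 ± 0.23), and so was stpA (-1.02 ± 0.20). Of 54 ribosomal protein genes 18 fell (camera adjusted p = 9.38e-14, adjusted p = 0.34 with an estimated correlation). Of 6 curli genes 5 rose (camera adjusted p = 3.42e-06, adjusted p = 0.0491 with an estimated correlation), with csgG at 1.19 ± 0.23. The list of ATP synthase and NADH dehydrogenase I had 4 of 22 genes higher (camera adjusted p = 3.21e-05, adjusted p = 0.42 with an estimated correlation), with nuoN at 2.03 ± 0.25 and nuoM at 1.69 ± 0.22. These lists had, adjusted over the list alone, 0 higher and 38 lower, 5 higher and 0 lower and 5 higher and 0 lower. Replicate 1 of this double mutant differs from the other libraries in having 21 genes without counts, against 82 to 267. Without it, 57 genes were higher and 24 lower, of which 54 and 22 were called the same way with all libraries. No ribosomal protein gene was then called, and 2 curli genes and 4 of the ATP synthase and NADH dehydrogenase list were. The count of all calls was 121 without hns mutant replicate 1, 98 without hns mutant replicate 2 and 427 without hns hha replicate 2. In the same order 3, 4 and 30 ribosomal genes fell and 2, 1 and 2 curli genes rose, and DESeq2 called 3 curli genes. The calls for csgG, stpA and tomB were lost without hns mutant replicate 2, and that for csgG also without hns hha replicate 1. With median-ratio size factors 55.8% of the calls were higher, against 44.0% with TMM.

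The hns ydgT double mutant against the hns mutant gave 222 higher and 375 lower genes (edgeR). With only the compared groups fitted it was 140 higher and 76 lower, and with DESeq2 212 and 201, so which direction has more genes depends on the method. The cnu gene had 0 counts in the double mutant (at least 6.51-fold lower), and rsxD, which lies near it and belongs to the operon that reduces the sensor SoxR, had a ratio of 0.0571 (95% counting interval 0.0115 to 0.173). Its operon mate rsxA was at -1.56 ± 0.42, and cadA at -3.51 ± 0.39. Of 54 ribosomal protein genes 40 fell, with a median of -0.89 (camera adjusted p = 3.34e-22, adjusted p = 0.192 with an estimated correlation), rplC at -1.69 ± 0.24. Of 9 type 1 fimbriae genes 6 fell (camera adjusted p = 8.93e-05, adjusted p = 0.0727 with an estimated correlation), with fimH at -1.20 ± 0.28. Of 14 beta-glucoside genes 5 rose and 1 fell (camera adjusted p = 2.55e-05, adjusted p = 0.0893 with an estimated correlation), with bglH at 2.09 ± 0.22. The genes of ATP synthase and NADH dehydrogenase I rose in 8 of 22 cases (camera adjusted p = 6.76e-07, adjusted p = 0.314 with an estimated correlation), with nuoN at 1088 ± 282 CPM against 207 ± 43.8 CPM. The 4 lists had, adjusted over the list alone, 0 higher and 48 lower, 0 higher and 6 lower, 5 higher and 1 lower and 10 higher and 0 lower. The acyl-CoA dehydrogenase gene fadE was at 2.59 ± 0.39. Both co-regulator genes left in the strain were lower than in the hns mutant, stpA at -1.36 ± 0.21 and hha at -0.77 ± 0.22. Against the hns mutant, the hns hha and hns ydgT strains shared 60 higher and 97 lower genes, where independent lists would share 7.28 and 15.6 and simulated unchanged groups shared 0. Without hns hha replicate 1 they shared 43 and 13 (3.44 and 2.40 for independent lists), and without hns mutant replicates 1 and 2 they shared 31 and 39, and 30 and 29. Without hns ydgT replicate 1 they shared 44 and 52. These overlaps with a library left out were chosen after the data were seen. Both comparisons use the same 2 hns mutant libraries, so part of the excess may come from them, which the simulations cannot measure. The count of all calls was 268 without hns mutant replicate 1, 332 without hns mutant replicate 2 and 157 without hns ydgT replicate 1. Ribosomal genes fell in 23 cases without hns mutant replicate 1 and 16 without hns ydgT replicate 1, where 4 genes of ATP synthase and NADH dehydrogenase I rose. Of the type 1 fimbriae genes 3 fell without hns mutant replicate 1 or either hns ydgT library. The lower beta-glucoside call was lost without hns mutant replicate 2 or either hns ydgT library and with DESeq2. The calls for rsxA (without either hns mutant library or hns ydgT replicate 1), fimH (without hns mutant replicate 1 or hns ydgT replicate 2) and hha (without hns mutant replicate 2 or hns ydgT replicate 2, and with DESeq2) were lost too. Across all genes the median log2 fold change was -0.11, and with median-ratio size factors 48.8% of the calls were higher, against 37.2% with TMM.

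The interactions asked whether removing the second gene acts differently with and without hns, as the difference between the 2 log2 fold changes. For stpA it differed in 969 genes, 493 more positive and 476 more negative without hns (edgeR). Of 15 acid resistance genes 14 were more negative (camera adjusted p = 5.67e-13, adjusted p = 0.0893 with an estimated correlation), with gadA at -4.01 ± 0.29 and hdeA at -2.44 ± 0.36. Of these 15 genes 12 rose in the stpA mutant against wildtype. In hns stpA against hns 1 was called higher and 3 lower (2 and 2 with median-ratio size factors). The more negative values thus do not show a fall of this list without hns. Of 20 colanic acid genes 15 were more positive (camera adjusted p = 3.76e-06, adjusted p = 0.0404 with an estimated correlation), with cpsB at 4.68 ± 0.60. Of 20 O-antigen and core genes 13 were more positive (camera adjusted p = 2.60e-05, adjusted p = 0.472 with an estimated correlation), with waaY at 4.17 ± 0.55. Of 22 genes of ATP synthase and NADH dehydrogenase I 17 were (camera adjusted p = 1.79e-07, adjusted p = 0.28 with an estimated correlation), with nuoH at 1.84 ± 0.24. The tdcE (-7.52 ± 0.45), tdcG (-7.29 ± 0.40), gudP (-8.97 ± 1.06) and cadA (-6.10 ± 0.55) genes were more negative. Adjusted over the list alone these 4 lists had 0 higher and 15 lower, 16 higher and 0 lower, 13 higher and 0 lower and 18 higher and 0 lower. The harvest density of the double mutant enters here too. So does the run from ybeU to gltI, which had 0 counts in the stpA mutant and counts in the hns stpA double mutant. A change carried by the stpA mutant alone would add to this interaction, and these data do not separate it. For hha, 15 genes were more positive and 34 more negative, maa (-5.22 ± 0.35), hha (-4.18 ± 0.46), cadA (-3.82 ± 0.55) and tomB (-3.13 ± 0.34) being the lowest. The hha value follows from the deletion, since hha had 570 and 725 counts in the hns mutant against 60 and 95 in wildtype. The maa and tomB genes lie beside it, so effects of the deletion on its neighbours are not separated. In this interaction 4 type 1 fimbriae genes were more negative (camera adjusted p = 1.55e-12, adjusted p = 0.0372 with an estimated correlation), with fimI at -2.32 ± 0.26. For ydgT, 55 were more positive and 69 more negative, among the latter rsxD (-4.41 ± 0.77, a fitted value that depends on the prior count because the double mutant held 3 counts) and cadA (-3.12 ± 0.56). In this interaction 21 of 54 ribosomal protein genes were more negative, and 46 adjusted over the list alone (camera adjusted p = 4.12e-29, adjusted p = 0.136 with an estimated correlation), with rplC at -1.80 ± 0.33. The cadA values of the 3 interactions use the same hns mutant and wildtype libraries, so they are not independent of each other. The count for hha was 15 without hns mutant replicate 2, 17 without hha mutant replicate 1, 20 without hns hha replicate 1, and 19 and 18 without wildtype replicates 1 and 2. Without wildtype replicate 2, 1 O-antigen and core gene was more negative in the stpA interaction.

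The count of the ydgT interaction also depended on single libraries. It was 37 and 41 without hns mutant replicates 1 and 2, 13 and 61 without ydgT mutant replicates 1 and 2, 14 and 243 without hns ydgT replicates 1 and 2, and 27 and 51 without wildtype replicates 1 and 2. The ribosomal count was 9 and 7 without hns mutant replicates 1 and 2, 2 and 12 without ydgT mutant replicates 1 and 2, 1 without hns ydgT replicate 1, and 1 and 5 without wildtype replicates 1 and 2. The call for rplC (-1.80 ± 0.33) was lost without hns ydgT replicate 1 or wildtype replicate 1, and that for rsxD (-4.41 ± 0.77) without ydgT mutant replicate 1 or hns ydgT replicate 1. With median-ratio size factors 56.7% of the ydgT calls were more positive, with DESeq2 61.5% and with only the compared groups 57.4%, against 44.4% with TMM.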

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

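Of the tests of explanations below, those on the stpA mutant and that of RNA from a strain with hns were chosen after the result was seen. The interaction tests gave 969 genes for stpA, 49 for hha and 124 for ydgT whose change differed with and without hns (edgeR, adjusted p under 0.05). In the stpA interaction the log2 values of the genes named were -6.10 ± 0.55 for cadA, 4.68 ± 0.60 for cpsB, -4.01 ± 0.29 for gadA, -8.97 ± 1.06 for gudP, -2.44 ± 0.36 for hdeA, 1.84 ± 0.24 for nuoH, -7.52 ± 0.45 for tdcE, -7.29 ± 0.40 for tdcG and 4.17 ± 0.55 for waaY. In the hha interaction they were -3.82 ± 0.55 for cadA, -2.32 ± 0.26 for fimI, -4.18 ± 0.46 for hha, -5.22 ± 0.35 for maa and -3.13 ± 0.34 for tomB. In the ydgT interaction they were -3.12 ± 0.56 for cadA, -1.80 ± 0.33 for rplC and -4.41 ± 0.77 for rsxD. The hha, maa and tomB values lie at or beside the deleted gene. The cadA values of the 3 interactions share the hns mutant and wildtype libraries, so they are not independent of each other. The stpA interaction is confounded with harvest density. The stretch without counts in the stpA mutant, which has counts in the double mutant, enters it as well.

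The stpA mutant had 9 neighbouring genes without counts, from ybeT, which had none in wildtype either, to gltI. Sampling at low depth is argued against by the 1235 counts that the wildtype level predicts for them in its 2 libraries. An effect of StpA loss with or without H-NS is argued against too, since 0 tested members were called lower in the hns stpA double mutant against the hns mutant, and all 9 had counts in the double mutant, although harvest density differed. Loss of this stretch of DNA in the strain remains a candidate explanation, since the nearest gene of at least 10 CPM in wildtype on each side, 2 of 2, lay within a log2 fold change of 1 of wildtype (ybeQ at -0.52 ± 0.26, lnt at 0.54 ± 0.17). Of these 2, lnt was itself called higher in the stpA mutant (edgeR adjusted p = 0.0413). Of the low-count genes between ybeQ or lnt and the run, djlB had 11 counts in the stpA mutant against 9 in wildtype. The others, ybeR and insH3, had 1 count each against 0 in wildtype, and ybeT had 0 in wildtype. The exact ends of the stretch therefore cannot be placed from these counts. No DNA sequence was available to test its loss, and an effect of StpA that needs H-NS stays open.

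The stpA mutant had 500 called genes although wildtype held 2 and 3 stpA counts. A single divergent stpA library as the source of most calls is argued against. At least 315 of the 500 were called the same way without either one (352 and 315), although 286 and 312 were without wildtype replicates 1 and 2. These fits assume that the lone library varies like the other groups, so divergence between the stpA libraries is not excluded. Their counts gave the highest chi-square per degree of freedom of the 8 replicate pairs (12.3, others 2.78 to 10.8). By Spearman correlation (0.974) the hns hha (0.971) and hns ydgT (0.963) pairs differed more. An equal effect of StpA with and without H-NS cannot be told apart from a differing one, because harvest density differed between hns stpA and hns: 41.6% of the 500, 208 genes, went the same way there (43 called higher and 39 lower in both, 93 higher then lower and 55 lower then higher). Heat shock genes were called higher in both (10 and 9 of 15), but the list had no call with an estimated correlation in stpA against wildtype (camera adjusted p = 5.07e-11, adjusted p = 0.125 with an estimated correlation) or hns stpA against hns (camera adjusted p = 0.0399, adjusted p = 0.644 with an estimated correlation). Another change in the strain, such as the missing stretch, or an effect of StpA that depends on H-NS may also account for the calls, and these data do not separate them.

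Replicate 1 of the hns hha double mutant had 21 genes without counts, against 126 in replicate 2. Its depth is argued against, since thinned to 419223 counts it had 65.2 such genes, against 199 to 362 in the other libraries. RNA of a strain that carries hns is argued against as the source of most of the extra counts. The hns count of replicate 1 allows up to 0.995% of such RNA. If all 772 counts in it of the 126 genes at 0 in replicate 2 came from RNA at the wildtype level, 64.1% would be needed. These genes were picked by their 0 counts in replicate 2 and no count was assigned to the strain itself, so that share may be overstated. A background over all genes, such as DNA, cannot be told apart from other causes: 79.1% of 278 low-count genes had at least 3 counts in it, against 7.96% to 48.0% in the other libraries, just under the 80% set before the result was seen. No biological explanation was tested, since the design gives none for 1 library of a group.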

How the results depend on the processing

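The alternatives of this part were chosen before the data were examined, except the list counts without hns hha replicate 1 and the overlaps with a library left out. Of 84 alternative counts of called genes, libraries left out aside, 74 lay within 1.5 times the main count and 10 moved. With DESeq2, 152 genes were called for hns hha against hns, 79 higher and 73 lower (284, 125 and 159 in the main analysis), and 3 for ydgT against wildtype (0). With only the compared groups, 22 were called for hha (12) and 6 for ydgT (0) against wildtype, 216 for hns ydgT against hns (597), 140 higher and 76 lower where the main analysis had 222 and 375, and 61 for the ydgT interaction (124). A log2 fold change of at least 1 left 313 for stpA against wildtype (500), 815 for hns stpA (1305), 160 for hns hha (284) and 310 for hns ydgT (597) against hns, fewer by its construction. The cause was not tested for the others.

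With each library left out in turn, where the lone library is assumed to vary like the other groups, the lowest and highest counts against wildtype were 1549 and 1578 for hns, 291 and 381 for stpA, 1 and 6 for hha, 0 and 0 for ydgT, 2053 and 2145 for hns stpA, 1566 and 2036 for hns hha, and 1419 and 1627 for hns ydgT. Against hns they were 925 and 995 for hns stpA, 81 and 427 for hns hha, and 157 and 505 for hns ydgT. For the interactions they were 727 and 833 (stpA), 15 and 62 (hha) and 13 and 243 (ydgT), and for genes higher in both hns and hns stpA 859 and 947 (990 in the main analysis). For counts of all calls and for overlaps, the libraries behind changes of over 1.5 times stand beside the result. The overlap of hns hha and hns ydgT, each against hns, ranged from 30 to 49 higher genes and 13 to 125 lower ones, lowest for lower genes without hns hha replicate 1.

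Median-ratio size factors shifted log2 fold changes by a median of 0.12 for hns stpA against wildtype and 0.11 against hns. The share of higher calls moved by over 10 points with them for hns hha (44.0% to 55.8%) and hns ydgT (37.2% to 48.8%) against hns and for the ydgT interaction (44.4% to 56.7%). With DESeq2 it was 51.3% for hns ydgT against hns, 61.5% for the ydgT interaction, 66.5% for hns ydgT against wildtype (55.8% with TMM) and 66.5% for hns stpA against hns (54.6%). Of 1256 alternative values of the 149 genes named per comparison, 1189 kept direction and side of the threshold, 66 lost the call, 1 gained it and 0 reversed. Replicate numbers did not pair the libraries (28 pairs of groups, r from -0.21 to 0.27 across genes, 4 over 0.1). The replicate block moved no count of calls by over 1.5 times (1910 for hns and 0 for ydgT against wildtype, 275 for hns hha against hns), and 155 of 157 camera calls were also made with it. Keeping rRNA genes was not run because the files hold none.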

Other observations

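The Rac prophage, with 16 genes higher in the hns mutant, had 9 higher and 7 lower in hns stpA against wildtype. With median-ratio size factors it had 11 and 6, and with DESeq2 10 and 6. Fewer were lower when any 1 library of these groups was left out, and the number higher varied too. Harvest density differed in this comparison. Some other lists that rose in the hns mutant were also higher in all 3 double mutants against wildtype. All 6 tested curli genes were called higher in each (camera adjusted p = 3.60e-04, adjusted p = 0.144 with an estimated correlation in hns stpA; camera adjusted p = 9.34e-07, adjusted p = 0.0525 with an estimated correlation in hns hha; camera adjusted p = 3.18e-05, adjusted p = 0.0727 with an estimated correlation in hns ydgT). The 9 activators, 10 carnitine metabolism genes and 3 proU genes were called higher in each too. For the activators the tests were camera adjusted p = 0.00342, adjusted p = 0.425 with an estimated correlation in hns stpA, camera adjusted p = 4.56e-06, adjusted p = 0.189 with an estimated correlation in hns hha and camera adjusted p = 9.54e-08, adjusted p = 0.138 with an estimated correlation in hns ydgT. For carnitine metabolism, in the same order, they were camera adjusted p = 2.18e-05, adjusted p = 0.0893 with an estimated correlation; camera adjusted p = 3.46e-04, adjusted p = 0.105 with an estimated correlation; and camera adjusted p = 0.00121, adjusted p = 0.122 with an estimated correlation. For proU they were camera adjusted p = 2.60e-05, adjusted p = 0.115 with an estimated correlation; camera adjusted p = 9.17e-06, adjusted p = 0.105 with an estimated correlation; and camera adjusted p = 1.91e-06, adjusted p = 0.0893 with an estimated correlation. Against wildtype, 16 of 20 colanic acid genes were called higher in hns hha (camera adjusted p = 6.68e-04, adjusted p = 0.195 with an estimated correlation) and 9 in hns ydgT (camera adjusted p = 0.196, adjusted p = 0.524 with an estimated correlation), or 5 in hns ydgT without wildtype replicate 2.

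The hns and stpA mutants shared 193 genes higher and 172 lower than wildtype, where independent lists would share 78.5 and 48.9 and simulated unchanged groups shared 0.05 and 0 on average, and 51 genes were called in opposite directions. Without wildtype replicates 1 and 2 they shared 110 higher and 112 lower, and 128 and 114 (36.1 and 21.1, and 43.1 and 21.8, for independent lists). Against the hns mutant, hns stpA and hns hha shared 81 higher and 81 lower genes (23.4 and 24.7 for independent lists, 0 and 0 simulated), with 16 in opposite directions. Without hns hha replicate 1 they shared 38 and 18 (10.7 and 3.77 for independent lists), and without hns mutant replicates 1 and 2 they shared 31 and 45, and 28 and 28. Without hns stpA replicate 2 they shared 55 and 49 (15.0 and 10.9 for independent lists). The overlaps with a library left out were chosen after the data were seen. The controls are too few to split, so part of each excess may come from the shared controls, which the simulations cannot measure. The 8 genes from ybeU to gltI, without counts in the stpA mutant, are among its lower genes. The missing stretch may therefore enter its overlap with the hns mutant.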
